A study of Mus musculus with 12 samples.

How the data were processed

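RNA was sequenced from mouse embryos and from cells cultured from them. Per the labels, 12 libraries fall into 4 groups of 3: control and knockout whole brain at embryonic day 15, and control and knockout primary neurospheres prepared at embryonic day 16. The knockout, called CKO here, removes the (pro)renin receptor in neural stem cells. All samples are labelled male and C57BL/6J. The abbreviation NSC is used for the neurosphere libraries. Per the labels' protocols, 500 ng of total RNA was depleted of ribosomal RNA, made into libraries with a kit that marks the strand, and read on a NextSeq 500.

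One table per tissue was used, each with 25655 genes. The values used as deposited are whole-number read counts per gene and library, with no normalization, per the file headers: reads over exons, uniquely placed reads over exons, reads spanning exon-exon junctions, and reads inside the gene but outside its exons. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10. Of 25600 gene identifiers found in GENCODE M21, which is on GRCm38, all lay on the same chromosome as in the tables, but only 564 had the same start and end and 1210 a start within 10000 bases. The listed coordinates therefore do not match GRCm38. They are given as the tables list them, and the build they are on is not given in the sources used here. Of the genes listed, 3731 had an exon length of 0 and no exon read, which left 21924. The tables held no blank or total lines.

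The authors' deposited tables also hold a comparison per gene, made with a test called EDGE with tagwise dispersions, per the file headers. Its p-value and its FDR-corrected p-value were deposited per gene. Its fold change was deposited as a signed score, which is CKO over control where positive and minus control over CKO where negative. Other deposited columns used here give annotation such as the gene identifier, chromosome, start, end, exon count and exon length. Another 120 columns of per-sample values in the same tables were not used.

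Exon counts were the main measurement. In each tissue the 6 libraries were fitted alone in edgeR 4.0.16 under R 4.3.3, with TMM normalization, the filterByExpr filter, robust quasi-likelihood dispersions (glmQLFit) and a two-sided quasi-likelihood F-test (glmQLFTest). Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called below 0.05. Fold changes are log2 values of CKO over control. Standard errors were taken as the absolute log2 fold change divided by the square root of F. Normalised CPM means use TMM factors and are given with the SD over 3 libraries. The difference between the 2 effects (an interaction term) and the comparison of control neurospheres with control brains came from 1 fit of all 12 libraries with 4 groups. Overlap of calls was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 4 pairs of directions. Replicate libraries of each group were compared gene by gene with a chi-square test over genes with at least 20 reads in the pair. Each pair differed by more than sampling noise, which does not show where the libraries came from. Each library was counted as 1 replicate, as labelled. The labels do not say whether replicates came from separate animals, litters or cultures.

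The test designs, the alternatives below, the rule for named genes and 31 gene lists were fixed before the data were examined. The lists cover V-ATPase subunits, lysosomal proteins and TFEB targets, autophagy genes, renin-angiotensin genes, Wnt/beta-catenin targets, the Notch pathway, neural stem cell and radial glia markers, intermediate progenitor markers, pan-neuronal markers, cortical glutamatergic neuron markers, inhibitory neuron markers, synaptic genes, astrocyte markers, oligodendrocyte lineage markers, S phase and G2/M genes of the cell cycle, p53 targets, unfolded protein response and ATF4 targets, cholesterol biosynthesis, hypoxia-inducible and glycolytic genes, iron uptake and storage genes, interferon-stimulated genes, microglia and macrophage markers, endothelial markers, pericyte and meningeal fibroblast markers, choroid plexus and ependymal markers, erythroid genes, mitochondrially encoded genes, cytosolic ribosomal proteins, immediate early genes and sex-linked check genes. Some genes stand in more than 1 list. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count of 2), two-sided, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Lists with at least 3 tested members entered. Camera with an estimated correlation and fry were alternatives. Calls adjusted over the list alone are given beside those over all genes.

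The rule for named genes took Atp6ap2 first. In each tissue it then took the 10 largest and the 10 smallest log2 fold changes among called genes with a mean of at least 1 CPM and groups that did not overlap. Symbols of the clone type were counted but not named, and 1 neurosphere gene that the rule took is not reported here. Within each list up to 4 members with the smallest adjusted p were named, whether or not they passed. For the interaction the 5 largest and 5 smallest terms were named, with the same minimum CPM and groups that did not overlap in at least 1 tissue. For neurospheres against brains up to 3 members per list were named.

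Alternatives planned in advance were RLE size factors in place of TMM, DESeq2 1.42.0, no filter on low counts, a mean of at least 1 CPM, an absolute log2 fold change of at least 1, library sizes without mitochondrial and haemoglobin genes, the replicate number as a block, all 12 libraries in 1 fit, and each library left out in turn. Chosen after seeing the data were uniquely placed reads, junction reads, an offset for GC content and length from GENCODE M21 transcripts, the intron share as a covariate, and leaving out both neurosphere libraries numbered 1. A change of the pseudocount was planned for normalized values only and does not apply to counts.

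The procedures were tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes given a change before filtering. For the brain comparison, run on 13434 genes, edgeR recovered 79.2% of genes changed 2-fold and 95.9% of those changed 4-fold and called 17 unchanged genes. For the neurosphere comparison, run on 13222 genes, it recovered 54.1% and 88.9% and called 15 unchanged genes. For the interaction, run on 14276 genes, it recovered 35.0% and 78.6% and called 10. In both tissues camera and fry called the changed set and 0 of 99 unchanged sets. The simulated genes were drawn independently of each other, so this does not show how the set tests behave where members move together. For S phase genes in neurospheres, the estimated correlation in the real libraries was 0.948. Figures were drawn with matplotlib 3.10.9.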

Results

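RNA was counted in 12 mouse libraries, 3 for each of control brain, CKO brain, control neurospheres and CKO neurospheres. Neurospheres are floating clusters grown from neural stem cells. The CKO removes the (pro)renin receptor, an accessory protein of the V-ATPase proton pump encoded by Atp6ap2, in neural stem cells. Control brains held 6675874, 5669338 and 6345029 exon reads and CKO brains 5874217, 6154400 and 5738810. Control neurospheres held 12482622, 12382975 and 14050572 and CKO neurospheres 14541492, 18636787 and 13167498. Reads inside genes but outside exons made up 63.8 to 65.5% of gene reads in brain and 7.64 to 14.06% in neurospheres. All p-values measure the spread between these libraries only, since the labels do not tell separate animals or cultures apart.

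Atp6ap2 was lower in CKO neurospheres and not detectably different in CKO brains. The gene (ENSMUSG00000031007) is listed with 9 exons and 2324 exon bases on chromosome X from 12454040 to 12483288, in coordinates that do not match those of GRCm38, on a build not given in the sources used here. Control brains held 63.96, 66.67 and 78.33 CPM (exon reads scaled to library size), and CKO brains 60.09, 68.41 and 65.0. Control neurospheres held 101.3, 96.75 and 95.23 CPM, and CKO neurospheres 61.55, 47.43 and 53.09. The log2 fold change was -0.12 ± 0.09 (SE, n = 3 per group) in brain (edgeR adjusted p = 0.792) and -0.81 ± 0.11 in neurospheres (adjusted p = 0.00965). The authors' deposited table gave signed fold changes of -1.09 in brain (FDR 1) and -1.749 in neurospheres (FDR 0.00102). The neurosphere call ended, at an adjusted p of 0.0570, without control 3 (log2 fold change -0.82) and without CKO 2 (-0.73). The labels do not say which part of the gene was deleted, so the counts cover the whole gene, reads of any remaining exons included.

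**Figure D1:**
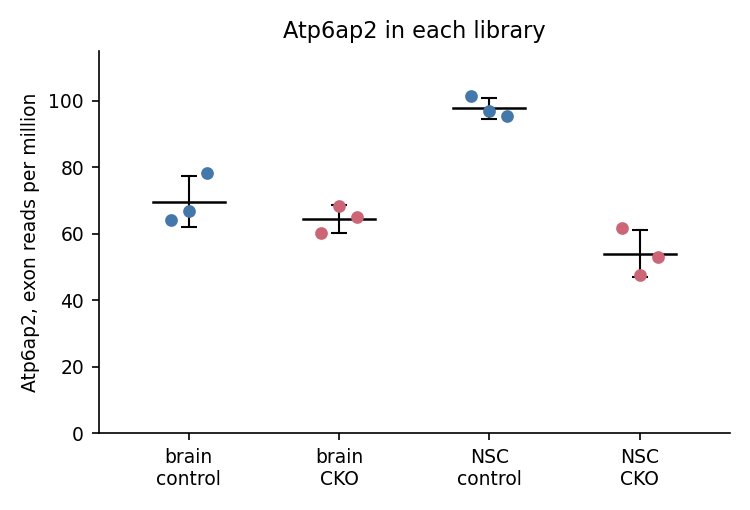
Exon reads of Atp6ap2 in CPM in each of the 12 libraries, with the mean and SD of each group of 3. In neurospheres the CKO libraries lie between 47.43 and 61.55 CPM, below all controls, while in brain the groups overlap.

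The brain comparison asks what differs between whole embryonic brains labelled CKO, in which Atp6ap2 itself was not detectably lower, and control brains. Of 32 targets of the unfolded protein response and the stress transcription factor ATF4, 10 rose, while 2 of 14 astrocyte markers and 4 of 22 neural stem cell and radial glia markers fell. Slc7a3, a transporter of cationic amino acids that is in none of the lists, rose from 0.991 ± 0.644 to 11.04 ± 0.886 normalised CPM (SD, n = 3), a log2 fold change of 3.48 ± 0.36 (SE; adjusted p = 0.00588). Chac1, which breaks down glutathione, rose by 2.75 ± 0.34 (adjusted p = 0.0104), Sesn2, a stress-induced inhibitor of mTORC1, by 1.36 ± 0.16 (0.00951), and Asns, asparagine synthetase, by 0.94 ± 0.13 (0.0138). Aldoc, an aldolase of astrocytes and radial glia, fell from 55.7 ± 4.81 to 28.7 ± 5.37 CPM (log2 fold change -0.96 ± 0.13; adjusted p = 0.0159).

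The other named genes that rose in CKO brains included 3 genes of microglia and macrophages. Ms4a6d had a log2 fold change of 3.07 ± 0.54, C3ar1, the receptor of complement C3a, 1.40 ± 0.23, and Fcrls 1.30 ± 0.20. Control brains held a mean of 0.215 CPM of Ms4a6d, so few reads set the size of its change. Egr1, an immediate early transcription factor, changed by 1.34 ± 0.23, the GTPase gene Rem2 by 0.89 ± 0.14 and the lipoprotein lipase gene Lpl by 0.81 ± 0.15. Among genes that fell, Ndrg2, expressed by astrocytes, went from 58.0 ± 8.50 to 30.5 ± 0.477 CPM (log2 fold change -0.92 ± 0.11). Aldh1l1, a folate enzyme used as an astrocyte marker, changed by -1.09 ± 0.16, and Mfge8, a secreted protein of radial glia and astrocytes, by -0.89 ± 0.16. Shisa3 (-1.54 ± 0.18), the lipase gene Lipg (-1.45 ± 0.20), the glycogen-targeting phosphatase subunit gene Ppp1r3c (-1.29 ± 0.20), Neb (-1.07 ± 0.18), the matrix gene Vit (-1.02 ± 0.18) and Lhx6 (-0.86 ± 0.15), a transcription factor of interneurons, also fell. These 15 genes had adjusted p-values of 0.00951 to 0.0480.

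Of 13557 genes tested in brain, 33 were higher and 27 lower in CKO, and 1187 had an unadjusted p under the threshold. For all 60, and for 14.4% of all tested genes, the groups did not overlap, where chance gives 10%. The authors' table listed 79 higher and 66 lower genes at the same threshold, among them all 60. The counts fell to 4 higher and 6 lower without control 1, 6 and 6 without control 2, 2 and 1 without control 3, 12 and 24 without CKO 1, 12 and 12 without CKO 2, and 6 and 9 without CKO 3. In these 6 fits every one of the 20 named genes kept its sign. The naming rule all but fixed that in advance, since it took only genes whose groups did not overlap. Slc7a3 alone passed in all 6 fits (highest edgeR adjusted p 0.0341), and the others reached up to 0.242. Of 6 further called genes named from the lists, Fabp7 alone passed in every such fit, and the others reached up to 0.227. With all 12 libraries in 1 fit, edgeR called 1 gene higher and 0 lower (300 and 223 at an unadjusted p), while DESeq2 on the 6 brain libraries called 58 and 55.

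**Figure D2:**
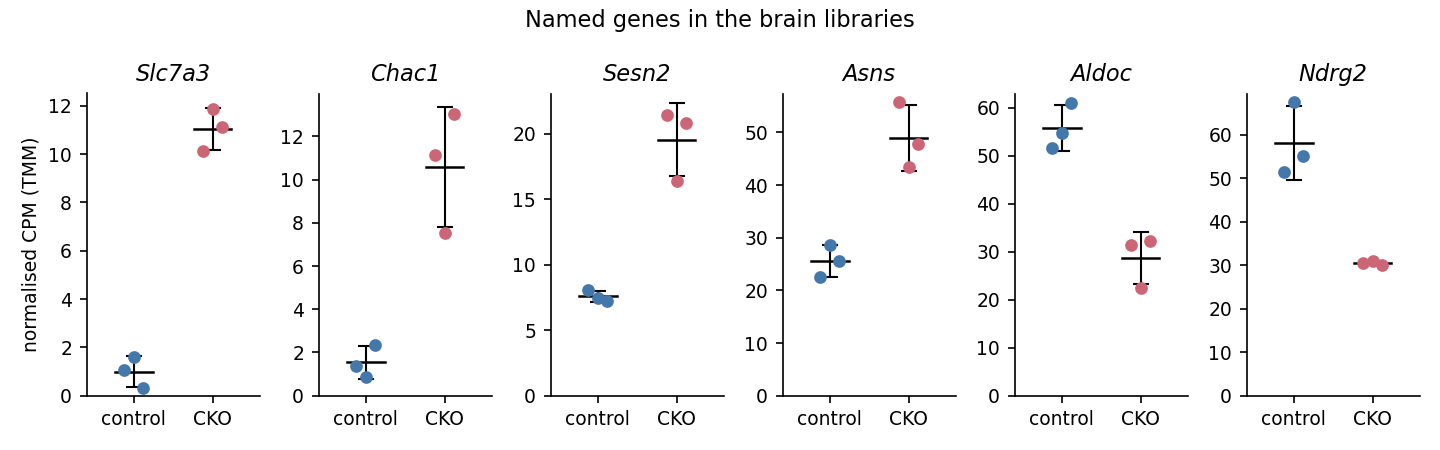
Normalised CPM of Slc7a3, Chac1, Sesn2, Asns, Aldoc and Ndrg2 in each brain library, with the mean and SD of 3 libraries per group. The first 4 genes were higher and the last pair lower in every CKO library than in any control.

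Among the 31 lists, the unfolded protein response and ATF4 targets had the lowest p in brain by camera with the preset correlation. With an estimated correlation and by fry these targets ranked behind the immediate early genes. Of 32 members, 10 rose and 0 fell, and 21 rose when adjusted over the list alone. The median log2 fold change was 0.43 (camera adjusted p = 5.55e-27; adjusted p = 0.255 with an estimated correlation). Beyond Chac1, Sesn2 and Asns, the list's named member was Slc7a5, an amino acid transporter (0.56). Of 43 genes of lysosomal proteins and TFEB targets, 0 passed by edgeR over all genes and 5 were higher when adjusted over the list alone. Their values were mostly positive, in 38 of 43, with a median of 0.20 (camera adjusted p = 6.56e-10; adjusted p = 0.294 with an estimated correlation), and the cathepsin gene Ctsd had 0.47. Of 19 p53 targets Sesn2 alone rose, by either adjustment, the second being adjusted over the list alone (camera adjusted p = 0.0291; adjusted p = 0.297 with an estimated correlation). That list lost its camera call without control 1 (adjusted p = 0.0559), CKO 1 (0.158) and CKO 3 (0.0648).

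Of 22 neural stem cell and radial glia markers 4 fell in CKO brains, namely Fabp7, a fatty acid-binding protein of radial glia (-0.79), Ptprz1 (-0.55), Ednrb (-0.67) and Mfge8, and 2 were higher and 8 lower when adjusted over the list alone (camera adjusted p = 3.30e-05; adjusted p = 0.297 with an estimated correlation). Of 20 cortical glutamatergic neuron markers Bcl11b fell (-0.50), and 6 fell when adjusted over the list alone, in a list with a median of -0.35 (camera adjusted p = 6.56e-10; adjusted p = 0.294 with an estimated correlation). Of 17 inhibitory neuron markers Lhx6 fell, and 1 was higher and 3 lower when adjusted over the list alone (camera adjusted p = 5.47e-05; adjusted p = 0.297 with an estimated correlation). Of 14 astrocyte markers Aldoc and Aldh1l1 fell, the same number as when adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.462 with an estimated correlation). Of 24 genes of S phase and 25 of G2/M, 0 passed by edgeR over all genes and 0 when adjusted over the list alone, yet all had positive values, with medians of 0.25 and 0.28 (camera adjusted p = 3.98e-07 and 3.48e-08; adjusted p = 0.500 with an estimated correlation for both).

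Of 23 pan-neuronal markers 0 passed in brain and 1 fell when adjusted over the list alone, Tubb3, neuronal tubulin, at -0.25 (camera adjusted p = 0.000101; adjusted p = 0.560 with an estimated correlation). Of 26 synaptic genes and 11 intermediate progenitor markers 0 passed, also when adjusted over the list alone. Their medians were -0.10 (camera adjusted p = 0.000861; adjusted p = 0.662 with an estimated correlation) and 0.12 (camera adjusted p = 0.0237; adjusted p = 0.560 with an estimated correlation). Without control 2 and without CKO 1 the camera calls ended for astrocyte markers (adjusted p = 0.109 and 0.219), pan-neuronal markers (0.0794 and 0.219), synaptic genes (0.171 and 0.596) and intermediate progenitor markers (0.171 and 0.489).

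Microglia and immediate early genes were higher as groups in the same CKO brains. Of 19 microglia and macrophage markers Fcrls rose, and 3 rose when adjusted over the list alone, with a median of 0.46 (camera adjusted p = 5.53e-06; adjusted p = 0.297 with an estimated correlation); the complement genes C1qa and C1qb had 1.24 and 0.93. Of 15 immediate early genes Egr1 rose, and 7 rose when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 1.53e-08; adjusted p = 0.252 with an estimated correlation). Atf3, a stress-induced transcription factor, had 1.94 and Nr4a1 had 1.09. Of 9 erythroid genes and 39 cytosolic ribosomal proteins 0 passed, also when adjusted over the list alone. Their medians were 0.16 (camera adjusted p = 0.0237; adjusted p = 0.440 with an estimated correlation) and 0.05 (camera adjusted p = 0.00262; adjusted p = 0.500 with an estimated correlation). The erythroid call ended without control 1 (adjusted p = 0.128) and without CKO 3 (0.205).

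The other 15 lists were not called in brain with all 6 libraries. Of 18 V-ATPase subunits, the complex that the receptor binds, Atp6v0a1 alone fell (-0.44), also when adjusted over the list alone (camera adjusted p = 0.727). The call of Atp6v0a1 over all genes ended whichever library was left out (edgeR adjusted p up to 0.219). Iron uptake and storage genes (0.183) held 3 members that passed when adjusted over the list alone and 0 over all genes. The haem oxygenase gene Hmox1 had 1.47 (adjusted p = 0.0976). No member passed by edgeR under either adjustment among autophagy genes (camera adjusted p = 0.607), renin-angiotensin genes (0.224), Wnt/beta-catenin targets (0.104), the Notch pathway (0.125), oligodendrocyte lineage markers (0.815), cholesterol biosynthesis (0.498), hypoxia-inducible and glycolytic genes (0.783) and interferon-stimulated genes (0.498). Neither did any among endothelial markers (0.180), pericyte and meningeal fibroblast markers (0.415), choroid plexus and ependymal markers (0.181), mitochondrially encoded genes (0.199) and sex-linked check genes (0.626). For oligodendrocyte, cholesterol and hypoxia genes in brain the median, mean and test differed in sign. Camera called further lists when 1 library was left out. These were renin-angiotensin genes (adjusted p = 0.0219) and mitochondrially encoded genes (0.0295) without control 1, Wnt/beta-catenin targets (0.0356) and the Notch pathway (0.0168) without control 2, and pericyte (0.0411) and choroid plexus markers (0.0483) without control 3. Without CKO 1 they were Wnt/beta-catenin targets (0.0212), the Notch pathway (0.0124), endothelial (0.0103), pericyte (0.0274) and choroid plexus markers (0.0140) and mitochondrially encoded genes (0.000308). Without CKO 2 renin-angiotensin genes were called (0.0266).

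The neurosphere comparison asks what differs in whole cultured neurospheres. Control neurospheres also expressed markers of other cell types, such as Dcx of neurons at 328.2 ± 75.93 normalised CPM (SD, n = 3). Changes can therefore not be assigned to the stem cells alone. In CKO neurospheres 22 of 24 S phase, 22 of 25 G2/M and 20 of 24 cholesterol biosynthesis genes rose, and 10 of 15 oligodendrocyte lineage and 11 of 23 pan-neuronal markers fell. Gpr17, a receptor of oligodendrocyte precursors, fell from 416.6 ± 354.6 to 1.72 ± 2.07 normalised CPM (SD, n = 3), a log2 fold change of -7.97 ± 1.68 (SE; adjusted p = 0.0211). Tnr, the matrix protein tenascin-R, fell from 567.8 ± 432.8 to 29.5 ± 4.07 CPM (-4.27 ± 0.84; adjusted p = 0.0180), and Sox10, a transcription factor of the lineage, from 156.5 ± 91.3 to 8.56 ± 6.92 CPM (-4.19 ± 0.93; adjusted p = 0.0233). Tm4sf1, a membrane protein, rose from 0.736 ± 0.102 to 9.36 ± 1.34 CPM (3.65 ± 0.26; adjusted p = 0.00755).

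Other named genes that fell in CKO neurospheres included an oligodendrocyte lineage marker, Bcas1. Its log2 fold change was -4.41 ± 1.01, that of Gal3st1, which makes the myelin lipid sulfatide, -5.94 ± 0.90, and that of the transcription factor gene Zfp488 -5.43 ± 0.85. Lims2 (-6.49 ± 1.08), the neuronal transcription factor gene Nhlh1 (-5.08 ± 1.06) and the claudin gene Cldn10 (-4.56 ± 1.05) fell too. Among genes that rose were those of the protease Mmp3 (5.41 ± 1.46), the chemokine Ccl2 (5.12 ± 1.21), the collagens Col6a3 (4.63 ± 1.32) and Col3a1 (4.27 ± 1.21), Srpx2 (3.83 ± 0.48) and osteopontin, encoded by Spp1 (3.32 ± 0.84). Saa3 (3.78 ± 0.73) and Lcn2 (3.76 ± 0.76), known as acute-phase genes, and the metalloreductase gene Steap4 (3.78 ± 0.62) rose too. Adjusted p-values of these 15 genes lay between 0.00890 and 0.0446. CKO libraries differed widely in some of them, as in Col3a1 with 237.2 ± 323.3 CPM. Control means were near the floor for Ccl2 (0.127 CPM), Srpx2 (0.149), Steap4 (0.176), Lcn2 (0.235) and Saa3 (0.308). CKO means were so for Gal3st1 (0.153), Nhlh1 (0.155) and Lims2 (0.264). Few reads therefore set the size of these fold changes.

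Of 13316 genes tested in neurospheres, 1958 were higher and 1595 lower in CKO, 50 of them with clone-type symbols, and 5713 had an unadjusted p under the threshold. The groups did not overlap for 3547 of the called genes and for 48.1% of all tested genes, where chance gives 10%. The authors' table listed 1499 higher and 1295 lower, and 2229 were called in both in the same direction. Leaving out 1 library moved the counts to 2850 higher and 2391 lower without control 1, and to 532 and 266 without control 2. Without CKO 3 they were 855 and 504. Without control 3 edgeR called 0 and 0 (2200 and 1977 at an unadjusted p), and without CKO 2 again 0 and 0 (2331 and 1951). All 20 genes taken by the naming rule kept their sign in these fits, as the rule's demand for groups that did not overlap all but ensures. Each lost its call in at least 1 fit, with edgeR adjusted p up to 0.139.

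The library labelled control 1 stood apart from the other control neurospheres. It held 1 read over 4 Y-linked genes, or 0.0801 CPM, against 2482 and 2992 reads, or 200.4 and 212.9 CPM, in controls 2 and 3, though all samples are labelled male. On the first principal component it lay at -5.81, with controls 2 and 3 at -61.56 and -52.78 and CKO libraries at 46.69, 38.51 and 34.96. Its intron share was 14.06% against 9.18 and 9.79%. Per degree of freedom, chi-square was 57.8 and 50.9 between it and controls 2 and 3, and 5.72 between those. CKO 1 differed from CKO 2 and CKO 3 by 30.6 and 37.4, and these from each other by 12.3. With both libraries numbered 1 left out, an alternative chosen after seeing the data, 3740 genes were higher and 3633 lower, and these held 1942 and 1586 of the genes called with all 6.

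**Figure D3:**
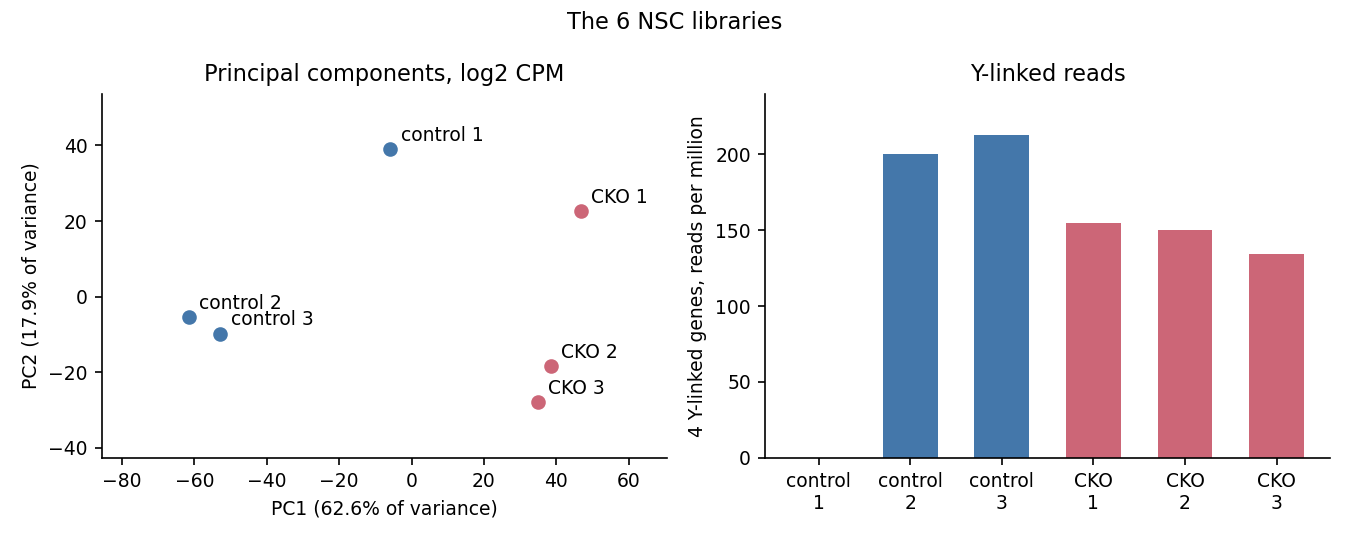
Left, the 6 neurosphere libraries on the first and second principal components of log2 CPM (62.6 and 17.9% of the variance); right, summed CPM of 4 Y-linked genes per library. The library labelled control 1 lies between the other controls and the CKO libraries on the first component and has 0.0801 CPM over the Y-linked genes.

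Most measured cell cycle and cholesterol synthesis genes rose in CKO neurospheres. Of 24 S phase genes 22 rose, 24 when adjusted over the list alone, with a median of 1.67, or 2.28 without control 1 (camera adjusted p = 1.55e-10; adjusted p = 0.736 with an estimated correlation). They included Pcna, the clamp of DNA polymerase (1.49), Tyms, thymidylate synthase (1.79), and Ccne1, cyclin E1 (2.12). Of 25 G2/M genes 22 rose, 24 when adjusted over the list alone, with a median of 1.41 (camera adjusted p = 5.63e-10; adjusted p = 0.736 with an estimated correlation), among them the mitotic kinases Aurka (1.79) and Plk1 (1.79). Of 24 genes of cholesterol biosynthesis 20 rose, 21 when adjusted over the list alone, with a median of 0.97 (camera adjusted p = 7.33e-12; adjusted p = 0.736 with an estimated correlation). Fdps, farnesyl diphosphate synthase, had 1.26, and Insig1, a sterol sensor, 1.13. Of 30 hypoxia-inducible and glycolytic genes 7 rose and 2 fell, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0395; adjusted p = 0.924 with an estimated correlation), with Ldha, lactate dehydrogenase, at 1.14 and Hk2, hexokinase, at 1.84. That call ended without control 1 (adjusted p = 0.179) and without CKO 2 (0.346).

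Of 15 oligodendrocyte lineage markers 10 fell in CKO neurospheres, 11 when adjusted over the list alone, with a median of -2.88 (camera adjusted p = 0.00156; adjusted p = 0.736 with an estimated correlation), among them Pdgfra, the growth factor receptor of precursors (-3.79). Without control 1 the median was -3.36 over the same 15 markers and -4.22 over the 17 then tested. Of 23 pan-neuronal markers 11 fell and 1 rose, or 13 and 1 when adjusted over the list alone (camera adjusted p = 0.000106; adjusted p = 0.784 with an estimated correlation), with the microtubule genes Dcx at -1.45 and Tubb3 at -1.14. Of 17 inhibitory neuron markers 7 fell, and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.736 with an estimated correlation), with Dlx1 at -2.14 and Dlx2 at -2.12. Of 20 cortical glutamatergic neuron markers 4 fell, the same number as when adjusted over the list alone (camera adjusted p = 0.00277; adjusted p = 0.736 with an estimated correlation), with Foxp2 at -1.54. Of 28 autophagy genes 11 fell and 1 rose, or 15 and 2 when adjusted over the list alone (camera adjusted p = 0.000985; adjusted p = 0.736 with an estimated correlation), with the initiation kinase Ulk2 at -0.83.

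Of 15 astrocyte markers 4 fell in CKO neurospheres, among them Apoe (-2.58), Aldh1l1 (-0.87) and S100b (-1.63), and Id3 rose (0.57), with the same counts when adjusted over the list alone (camera adjusted p = 0.0375; adjusted p = 0.822 with an estimated correlation). The astrocyte call ended without control 2 (adjusted p = 0.0665), control 3 (0.0539) and CKO 1 (0.104). Of 26 synaptic genes 4 fell, with the adhesion gene Nlgn1 at -1.09 and Syt4 at -1.07, and 1 rose (camera adjusted p = 0.00958; adjusted p = 0.822 with an estimated correlation). When adjusted over the list alone 0 passed, by edgeR, and the camera call ended without control 1 (adjusted p = 0.144) and CKO 3 (0.0561).

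The remaining 19 lists tested were not called in neurospheres with all 6 libraries. Of 32 unfolded protein response and ATF4 targets 9 rose and 1 fell, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.119), with the folate enzyme gene Mthfd2 at 1.34 and the chaperone gene Hspa5 at 0.71. Among Wnt/beta-catenin targets (0.0587) Lef1 (2.31), Tcf7 (1.74) and Axin2 (0.78) rose, also when adjusted over the list alone. Intermediate progenitor markers (0.0587) held 3 that fell, namely Neurod1 (-1.28), Neurog2 (-2.75) and Elavl4 (-0.48), or 4 when adjusted over the list alone. In the Notch pathway (0.119) the ligand genes Dll3 (-2.62) and Dll4 (-1.27) fell with Maml2 (-0.33) and Jag1 rose (2.18), also when adjusted over the list alone. Neural stem cell and radial glia markers (0.601) had 2 that rose, Gli3 (0.55) and Tnc (0.89), and 2 that fell, Ptprz1 (-0.62) and Mfge8 (-1.50), or 4 and 3 when adjusted over the list alone. Pericyte and meningeal fibroblast markers (0.210) had 3 that rose, Foxc1 (2.31), Rgs5 (1.22) and Col3a1, or 7 when adjusted over the list alone. In the list of 7 renin-angiotensin genes (0.940) Atp6ap2 fell and Ace rose (1.99), also when adjusted over the list alone.

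V-ATPase subunits as a list were not called in neurospheres (camera adjusted p = 0.988), though Atp6v0a1 (-1.19), Tcirg1 (-0.84) and Atp6v0d1 (-0.30) fell, 2 of them when adjusted over the list alone. Of 43 lysosomal proteins and TFEB targets (0.629) 2 rose and 3 fell, the latter Ctsf (-1.55), Npc1 (-0.50) and Scarb2 (-0.74), or 0 and 2 when adjusted over the list alone. Rrm2b among p53 targets fell (-0.57; list 0.629), as did Cfap126 among choroid plexus and ependymal markers (-1.84; list 0.765), while Rps2 among cytosolic ribosomal proteins rose (0.44; list 0.914). Of the iron genes Steap3 rose (1.74) and Ireb2 fell (-0.29; list 0.686), and in these 4 lists 0 members passed by edgeR when adjusted over the list alone. Interferon-stimulated genes (0.0569), mitochondrially encoded genes (0.856), immediate early genes (0.418), sex-linked check genes (0.526), 3 microglia and macrophage markers (0.765) and 4 endothelial markers (0.30) held 0 that passed either way. No erythroid gene had enough reads to be tested. For V-ATPase, lysosomal, mitochondrial and ribosomal genes the median, mean and test differed in sign.

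In neurospheres too, camera called further lists when 1 library was left out. Without control 1 these were p53 targets (adjusted p = 0.000787), immediate early genes (0.00189), Wnt/beta-catenin targets (0.0259) and intermediate progenitor markers (0.0296). Interferon-stimulated genes were called without control 2 (0.0375), CKO 1 (0.000789) and CKO 2 (0.0162). Unfolded protein response and ATF4 targets were called without control 3 (0.0474), the Notch pathway (0.0480) and pericyte markers (0.0289) without CKO 2, and intermediate progenitor markers without CKO 3 (0.0269).

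**Figure D4:**
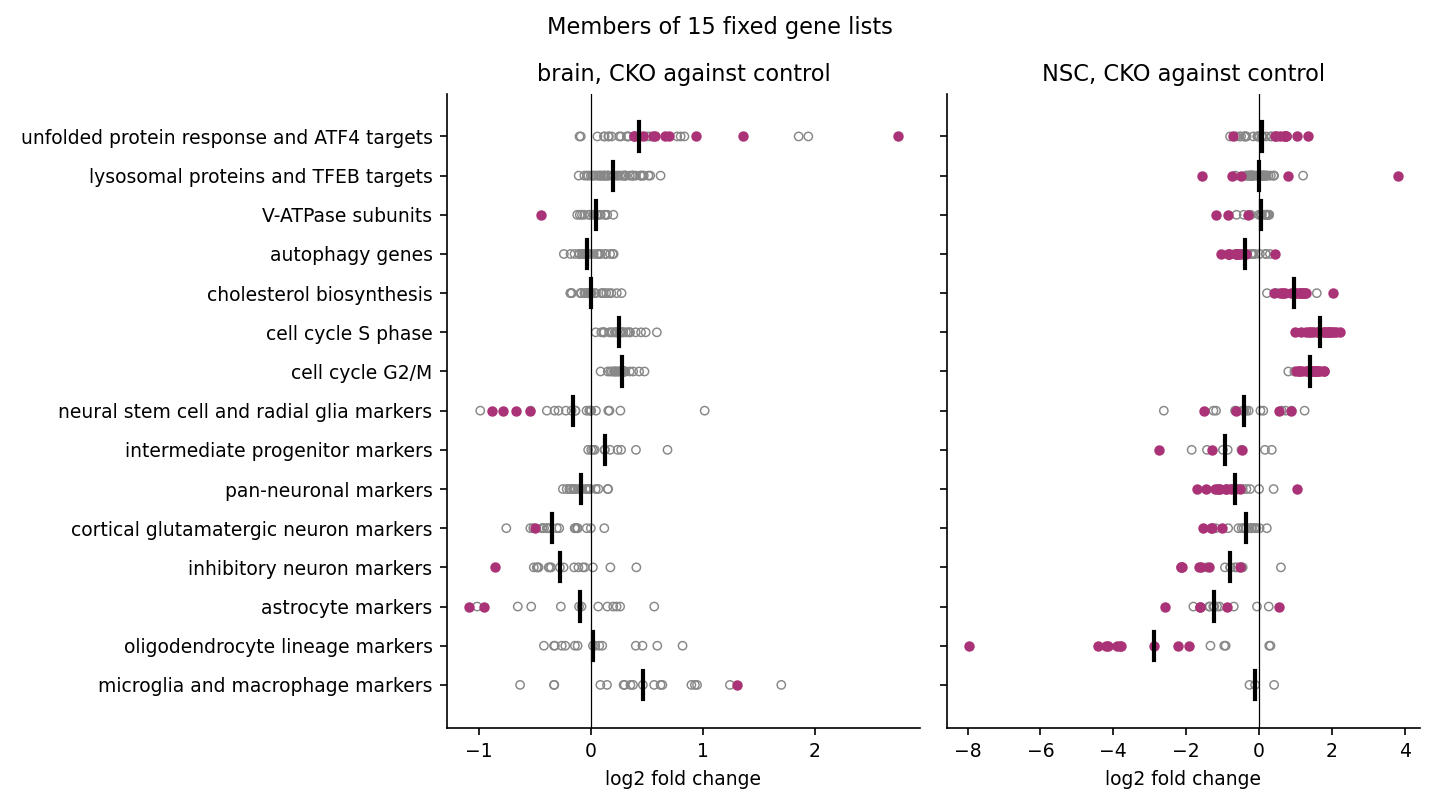
Log2 fold change (CKO over control) of each tested member of 15 lists in brain and in neurospheres, on axes of different range. Magenta filled points have an adjusted p under 0.05, open grey points do not, and black bars are medians, such as 0.43 for the unfolded protein response and ATF4 targets in brain and 1.67 for S phase in neurospheres.

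The difference between both effects shows where the response in neurospheres departed from that in brain. Its fit gave each gene 1 dispersion for both tissues, although the common biological coefficient of variation was 0.098 in brain and 0.222 in neurospheres. In that fit edgeR called 1 gene higher in CKO brains, against 33 in brain alone. For CKO neurospheres it called 2935 higher, against 1958. The p-values of the difference rest on this shared dispersion. Culture, embryonic day and RNA make-up also differ with the tissue and cannot be told apart from it. Among genes that passed, the most negative differences were those of Lims2 at -6.09 ± 1.38 (SE; adjusted p = 0.0189) and the sulfatide enzyme gene Gal3st1 at -5.89 ± 1.16. Next came Zfp488 at -5.63 ± 1.11, Nhlh1 at -5.29 ± 1.03 and Bcas1 at -4.88 ± 1.32. CKO neurospheres held means of 0.264 CPM of Lims2, 0.153 of Gal3st1 and 0.155 of Nhlh1, so few reads set the size of these terms. Shisa3 changed in opposite directions in the separate fits, falling in brain and rising in neurospheres, with a difference of 4.14 ± 0.58 (adjusted p = 0.00440). Fap, a protease of activated fibroblasts, had 4.47 ± 1.22. Terms for the histone gene H2ac11 (5.85) and for Tph2 (4.34), which makes serotonin, depend on the prior count, since neither gene had a read in control neurospheres. The term for Prnd (4.20), with 1 read there, does so too. In brain 31.9% of H2ac11 reads were uniquely placed and 6.20% of Prnd reads, so reads of other genes enter both. Of 14415 genes tested 1040 had a positive and 873 a negative term, 1913 in all, with 4507 at an unadjusted p. Atp6ap2 itself differed by -0.68. The count was 4003 without neurosphere control 1, 1047 without control 2, 971 without control 3, 1035 without CKO 2 and 4912 without both numbered 1. It was 917 without brain control 1, 1130 without control 2, 924 without control 3, 877 without CKO 2 and 846 without CKO 3.

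By list, 12 of 31 differed between the tissues. Cholesterol biosynthesis (camera adjusted p = 4.34e-16; adjusted p = 0.0879 with an estimated correlation), S phase (1.41e-11; adjusted p = 0.627 with an estimated correlation) and G2/M (1.02e-09; adjusted p = 0.634 with an estimated correlation) had higher terms in neurospheres. Oligodendrocyte lineage markers (9.52e-05; adjusted p = 0.603 with an estimated correlation) and pan-neuronal markers (9.52e-05; adjusted p = 0.662 with an estimated correlation) had lower ones. Unfolded protein response and ATF4 targets as a list were not shown to differ (camera adjusted p = 0.0713), though its members Chac1 (-3.09), Sesn2 (-1.36) and Asns (-0.83) were. Slc7a3, outside the list, differed by -4.19.

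Aldh1l1, an astrocyte marker, and Mfge8 and Ptprz1, markers of radial glia, were among the genes that fell in both tissues. The 11 shared genes were Aldh1l1, Atp6v0a1, Kcnq3, Lhx6, Mfge8, Ndrg2, Ptprz1, Ttc28, Ttyh1, Vit and Zeb2, where 3.29 would be shared by chance among 12763 genes tested in both (Fisher's exact test, adjusted p = 0.000693). Shared higher genes were Aars, Atf4, Copb2, Hspa5, Kdelr2, Lpl, Morf4l2, Mthfd2 and Srpr, 9 against 4.36 by chance (Fisher's exact test, adjusted p = 0.0567). Only Shisa3 was lower in brain and higher in neurospheres (1 against 4.06; adjusted p = 0.111), and 0 genes were higher in brain and lower in neurospheres (0 against 3.54; adjusted p = 0.0567). Across the 12763 genes, log2 fold changes correlated with Pearson's r = 0.271 and Spearman's rho = 0.318. Genes are not independent replicates, which limits these values and Fisher's exact tests alike. Of 56 genes called in brain 47 had the same sign in neurospheres. The share with the same sign over all 12763 genes was not counted, so the 47 have no baseline. The overlap of lower genes did not pass without brain control 2 (adjusted p = 0.637, with 6 lower genes called in brain), brain CKO 2 (0.196, with 12), neurosphere control 2 (0.0669), CKO 1 (0.0508) and CKO 3 (0.165). Without brain control 3, which left 1 lower gene in brain, and without neurosphere control 3 or CKO 2, which left 0 by edgeR (1977 and 1951 lower at an unadjusted p), too few genes were called for the test to say anything. That of higher genes passed without neurosphere control 1 (0.0267) and CKO 3 (0.0399).

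The comparison of control neurospheres with control brains gives the background of both effects. Of 16 oligodendrocyte lineage markers 13 were higher in neurospheres, with Olig1 at 5.78 ± 0.41 and Olig2 at 4.87 ± 0.23 (SE), and of 16 astrocyte markers 14 were, with Apoe at 6.88 ± 0.61. The camera adjusted p was 0.00126 for the first (adjusted p = 0.352 with an estimated correlation) and 0.000119 for the second (adjusted p = 0.352 with an estimated correlation). Neural stem cell and radial glia markers had 13 higher and 4 lower of 22, with the glutamate transporter gene Slc1a3 at 3.48 ± 0.19 (camera adjusted p = 0.0353; adjusted p = 0.500 with an estimated correlation). Of 23 pan-neuronal markers 18 were lower, with Dcx at -2.48 ± 0.24 (camera adjusted p = 9.10e-05; adjusted p = 0.466 with an estimated correlation). All 15 endothelial markers were lower, with Pecam1 at -5.51 ± 0.20 (camera adjusted p = 7.18e-08; adjusted p = 0.0285 with an estimated correlation), as were 18 of 20 microglia and macrophage markers (camera adjusted p = 3.25e-05; adjusted p = 0.138 with an estimated correlation). In all 5028 genes were higher and 5118 lower in neurospheres, and the tissue cannot be told apart from the embryonic day, which differs by 1 day, nor from the make-up of the RNA, with a mean intron share of 64.9% in control brains and 11.0% in control neurospheres.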

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

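Tests of the library labelled control 1 as the source of the neurosphere pattern, of cell shares, of microglia and of dissection stress were chosen after the results were seen, as was the count on intron reads. The other tests here were written before their own results were seen. The GC and length offset was still chosen after the data were seen, and the tests of Y-linked reads address a pattern already seen.

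The effect of the CKO differed between neurospheres and brain, by a test of the difference itself, for 1913 genes. That test shares 1 dispersion per gene between tissues of unlike spread. Culture, embryonic day and RNA make-up differ with the tissue and cannot be told apart from it. On the log2 scale, the effect in neurospheres less that in brain was -0.68 for Atp6ap2, -4.19 for Slc7a3, -3.09 for Chac1, -1.36 for Sesn2, -0.83 for Asns and -1.83 for Rem2. For genes named in neurospheres it was 3.11 for Srpx2, 6.25 for Steap4, 3.14 for Tm4sf1 and -4.06 for Tnr. Control neurospheres held means of 0.149 CPM of Srpx2 and 0.176 of Steap4, so few reads set the size of both differences. The difference was 4.14 for Shisa3, 4.47 for Fap, -6.09 for Lims2, -5.89 for Gal3st1, -5.63 for Zfp488, -5.29 for Nhlh1 and -4.88 for Bcas1. The values for H2ac11 (5.85), Tph2 (4.34) and Prnd (4.20) depend on the prior count, since control neurospheres held at most 1 read of each.

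As lists, the difference was called by camera for cholesterol biosynthesis (adjusted p = 4.34e-16), S phase (1.41e-11), G2/M (1.02e-09), oligodendrocyte lineage markers (9.52e-05), pan-neuronal markers (9.52e-05) and autophagy genes (0.000209). It was also called for Wnt/beta-catenin targets (0.00203), lysosomal proteins and TFEB targets (0.00352), inhibitory neuron markers (0.00659), intermediate progenitor markers (0.00731), hypoxia-inducible and glycolytic genes (0.00885) and synaptic genes (0.0423). None of the 12 passed with an estimated correlation, where the lowest adjusted p was 0.0879, for cholesterol biosynthesis.

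Of 100 splits drawn from 200 that exchange labels within each tissue, 11 gave an interaction count as large as the real one, which was 1913, and the highest other gave 3128. The 10 others all keep the neurosphere labels and differ in the brain labels alone, so chance is not excluded this way and the count follows the neurosphere groups. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, the only 1 as large in each case, gave 60 genes in brain with 2 as the highest other, 3553 in neurospheres with 0, and 9571 between control tissues, fitted alone, with 0.

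Reads inside genes but outside exons, which the comparisons do not use, also differed between CKO and control. With them edgeR called 42 genes in brain and 235 in neurospheres.

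The neurosphere library labelled control 1 held 1 Y-linked read. Shallow sequencing would not give this, since at its depth controls 2 and 3 predict 2580 such reads. Cells from a female embryo would carry more RNA from X-linked genes that escape inactivation, and the median log2 ratio of 5 such genes against controls 2 and 3 was 0.599 (SD 0.197), from 0.155 for Ddx3x to 0.624 for Kdm6a. Loss of the Y chromosome without a second X would leave those genes level, but the median exceeds the largest ratio between controls 2 and 3 by 0.46. A female embryo or a mixed-up sample may therefore be the source, with the reserve that 0.599 is at percentile 86.6 of all genes, and this library differs broadly from the other controls. Xist and Tsix, the X-linked members of the sex-linked check genes, were not among the genes listed. A direct check for a second X chromosome through Xist was therefore not possible.

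In CKO neurospheres cell cycle and cholesterol genes were higher and oligodendrocyte and neuronal genes lower. The tables argue against the library labelled control 1 as the source, since without it the S phase median was 2.28 instead of 1.67, and against GC content and gene length, since with that offset it was 1.73. A lower share of oligodendrocyte lineage cells and neurons alone would raise alike the genes found only in the remaining cells. The S phase median exceeded that of 22 stem cell and radial glia markers by 2.07, when these had a median of -0.41 (SD 0.90). That cannot decide the question, since markers shared with the lost cells would not rise alike, and which cells express each marker was not measured. More proliferating cells after loss of the receptor may account for part of the pattern, though 11 replication-dependent histones had a median of -0.70. Of that family 60 were tested in brain, so most had too few reads in neurospheres to be tested. The 11 histones left therefore cannot decide for or against proliferation. Differences between cultures in growth, density or date were not tested, because the labels do not give them.

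In CKO brains the unfolded protein response and ATF4 targets were higher, which GC content and gene length do not account for, with a median of 0.39 under the offset instead of 0.43. More microglia in the CKO brains cannot be told apart from a change within cells, because more cells of a type can raise a gene by up to the fold of their markers, and the median of the targets less that of the microglia markers was -0.03 (SD over markers 0.59); of the most abundant markers Mrc1 went from 26.9 to 34.4 CPM, Csf1r from 22.2 to 27.2 and Sall1 from 82.4 to 65.7. The markers gained 33.0 ± 4.59 CPM in sum (SE), from 206.3, and the targets 516 ± 85.5, from 1981. These sums cannot decide the question, since Sall1 held 82.4 of the 206.3 CPM and fell, while 16 of 19 markers had positive values. The level of the targets in microglia was not measured either. Stress during dissection cannot be told apart from an effect of the CKO, because immediate early genes had a median of 0.442 in the same brains and no library separates handling from genotype. A stress response to loss of the receptor may be at work and stays open with both, although Atp6ap2 itself was not detectably lower in these brains (-0.12; adjusted p = 0.792).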

How the results depend on the processing

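Uniquely placed reads, junction reads, the GC and length offset, the intron covariate and leaving out both neurosphere libraries numbered 1 were chosen after the data were seen. Of passing genes taken by the naming rule none reversed under any alternative run. Where the groups of a gene did not overlap, leaving out 1 library could hardly reverse its sign. In brain 303 of 436 such results kept their call and 133 lost it. In neurospheres 1320 of 1691 kept it and 371 lost it, and for the interaction 152 of 190 and 38. Brain counts of 33 higher and 27 lower became 7 and 6 with a log2 fold change of at least 1, 58 and 55 with DESeq2, 108 and 85 with the replicate number as a block, 1 and 0 with all 12 libraries in 1 edgeR fit (300 and 223 unadjusted), 11 and 15 with junction reads and 66 and 73 with the intron share as covariate. With 1 library left out they ranged from 2 to 12 and from 1 to 24. Neurosphere counts of 1958 and 1595 became 530 and 573 with a log2 fold change of at least 1 and 3740 and 3633 without both libraries numbered 1; the lower count became 2813 in the fit of 12 and 2618 with the intron covariate. With 1 library left out they ranged from 0 to 2850 and from 0 to 2391. The interaction count of 1913 became 636 with the fold threshold and 4912 without both libraries numbered 1, and ranged from 846 to 4003 with 1 left out. Atp6ap2 in neurospheres ranged from -0.90 to -0.73 with 1 library left out and was -1.04 with junction reads. Of 16 lists called in brain and 11 in neurospheres, 0 and 0 passed by camera with an estimated correlation and 3 and 1 by fry; the block called 15 in neurospheres and leaving out both numbered 1 called 14. The 20 genes that moved the same way in both tissues became 51 with DESeq2, 71 with the block and 40 without both libraries numbered 1, with 0 to 31 when 1 was left out. The adjusted p for genes higher in both became 0.000333 with DESeq2, 0.00229 with no filter, 9.75e-06 with the block and 0.000416 without both libraries numbered 1, and 0.0267 to 1 with 1 left out; for genes lower in both that range was 1.33e-08 to 1. Without brain control 3, neurosphere control 3 or CKO 2, at most 2 genes per direction were called in 1 tissue, so the counts of 0 and the p of 1 there say nothing of the overlap. Without both libraries numbered 1 the Y-linked Ddx3y (-0.34) and Eif2s3y (-0.53) reversed in neurospheres, since the library without Y-linked reads is then out. Fewer genes pass a fold threshold by its construction; for the other changes the cause was not tested. The basis of the block is uncertain, since deviations of libraries with the same number correlated by -0.04 to 0.41 and not always best with each other. On the first principal component of the brain libraries (33.1% of the variance), however, libraries with the same number lay near each other. Control and CKO lay at -17.23 and -28.48 for number 1, at 15.42 and 17.94 for number 2, and at 5.96 and 6.39 for number 3. A mean of at least 1 CPM removed no gene tested in brain, so it says nothing there. Brain libraries held at most 6675874 exon reads, which limits genes with few counts.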

Other observations

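The gene families below, and the use of intron reads, were chosen after the results were seen. The test of intron sign was written before its result.

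Besides the fixed lists, gene families were tested in CKO brains. Of 19 subunits of the COPI and COPII coats, which carry vesicles between endoplasmic reticulum and Golgi, 18 had positive values and Copb2 rose (log2 fold change 0.53; family median 0.24; camera adjusted p = 2.66e-11; adjusted p = 0.0459 with an estimated correlation). Of 19 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, Cars (0.62), Nars (0.40), Iars (0.41) and Aars (0.33) rose (camera adjusted p = 5.35e-10; adjusted p = 0.201 with an estimated correlation). Replication-dependent histones had 55 of 60 positive values, and 0 passed by edgeR (camera adjusted p = 1.24e-06; adjusted p = 0.763 with an estimated correlation). Of 78 mitochondrial ribosomal proteins 0 passed in brain either (camera adjusted p = 0.114). Proteasome subunits, complex I subunits, collagens and subunits of the chaperonin TRiC were not called in brain (camera adjusted p from 0.305 to 0.522).

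In CKO neurospheres 27 of 37 proteasome subunits rose, with Psmd13 and Psmc5 at 0.63 each (camera adjusted p = 1.40e-11; adjusted p = 0.148 with an estimated correlation). Of 78 mitochondrial ribosomal proteins 34 rose, with Mrpl12 at 1.12 (camera adjusted p = 1.40e-11; adjusted p = 0.148 with an estimated correlation). The chaperonin TRiC, which folds actin and tubulin, had 7 of 8 subunits that rose, with Tcp1 at 0.68 (camera adjusted p = 1.14e-05; adjusted p = 0.0998 with an estimated correlation). Of the aminoacyl-tRNA synthetases 11 rose (camera adjusted p = 1.45e-05; adjusted p = 0.167 with an estimated correlation), and of 37 subunits of respiratory complex I 13 did (camera adjusted p = 8.91e-06; adjusted p = 0.312 with an estimated correlation). Of 19 COPI and COPII coat subunits 4 rose in neurospheres too (camera adjusted p = 0.0490, or 0.183 with an estimated correlation). Their effect was not shown to differ between the tissues (camera adjusted p = 0.326). Collagens went both ways, with 10 higher and 4 lower (camera adjusted p = 0.195). Of 11 replication-dependent histones tested 1 rose and 2 fell, with a median of -0.70 (camera adjusted p = 0.177).

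Intron reads can come from unspliced RNA, but their source was not measured here. In brain they were called lower for Acss1 (log2 fold change -0.80), Vit (-1.01) and Sh3rf3 (-0.83) and higher for Mthfd1l (0.70) and Eif2ak3 (0.58), a kinase of the unfolded protein response. In neurospheres they were lower for Cadm2 (-1.75) and Alcam (-1.99) and higher for Fdps (1.23). They were also lower for Myh6 (-3.04) and Olfr1511 (-2.81), which had too few exon reads to be tested. Intron reads therefore need not follow the exons of the same gene. Across genes, which are not independent replicates, intron and exon fold changes correlated with r = 0.576 in brain and 0.812 in neurospheres, and 10 and 191 genes were called by both. If transcription rather than RNA turnover changed, called brain genes would keep their sign in introns, and 55 of 56 with enough intron reads did (98.2%). That is consistent with a change in transcription, as a hypothesis, and leaves open other changes that alter both read classes.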
